A study of Homo sapiens with 4 samples.

How the data were processed

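RNA-seq libraries of a clonal BJ-5ta line with doxycycline-inducible FOXA2 were described by their labels as 2 uninduced and 2 induced samples (0.5 µg/ml doxycycline). RNA was extracted with a column kit, and libraries were made with a TruSeq kit that does not keep strand and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. How long the cells were induced, and which cultures received mimosine, is not stated in the labels. Reads were aligned with TopHat to hg19, per the submitters' processing notes; the version, the quantifier and the filters are not given in the sources used here.

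The deposited values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, with a lower and an upper confidence bound, per the file headers. The table has 63651 rows with Ensembl identifiers and 56620 gene symbols, and 1 FPKM column for each group. Whether a column combines both samples of its group, and the level of the confidence intervals, is not stated. The columns were matched to groups by name, and 3 value columns of 1 further condition that matches no sample used here were left out of every step. Coordinates are those of the table, counted from 1. A row's locus can span neighbouring genes.

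The planned tests, limma on log2 values of 4 libraries and camera for gene lists, could not be run with 1 value per group. In their place a gene was said to rise or fall when the deposited intervals of the 2 columns did not overlap, and 3 kept genes with malformed bounds were never called. This criterion, and the filter in its present form, were set after the format of the table and part of its values had been seen. Genes were kept at 1 FPKM or more in at least 1 of the 2 columns (planned: at least 2 of 4 libraries), which left 14319. Log2 differences are induced minus uninduced on the log2(FPKM + 1) scale, which understates the change of genes with low values.

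The 31 gene lists, all but the added alternatives, and the rule for named genes were fixed before the data were examined. For the 21 lists with at least 5 kept genes the median log2 difference was placed among 10000 random lists, in which each member was replaced by 1 of the 100 genes nearest to it in mean log2 expression, and was said to lie outside when beyond the central 95%. The matching was first run in 20 expression bins (4 lists above and 4 below their ranges) and was then changed to the 100-gene window, because the highest bin was too coarse for the ribosomal genes. This choice was made after the results had been seen, and moved the count to 5 above and 3 below. The random lists hold unrelated genes, so their ranges are narrower than those of genes regulated together, and they describe these 2 columns without testing the conditions. Some lists share members: GDF15 and SESN2 are in the p53 and the ATF4 lists, and UHRF1 is in the G1/S and the DNA methylation lists. ATF3 is in the ATF4 and the immediate early lists. RPLP0, PGK1 and SDHA of the housekeeping list are also in the ribosomal, the glycolysis and the respiratory chain lists, in that order.

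The rule for named genes took FOXA2, then the 10 genes with the largest log2 difference in each direction among genes that rose or fell. The planned condition that both induced libraries lie on the same side of both uninduced ones could not be applied. Symbols that start with a fixed set of prefixes of clone, locus and small RNA names (such as CTD-, LOC, LINC, MIR, SNOR and RNU) and sex-specific genes were left out. The set did not cover every such symbol, so that AC118278.1, a clone name, and snoU13, a small nucleolar RNA, were named under the rule. For each list tested the rule then took up to 4 members that rose or fell, or, with none, the 2 with the highest FPKM. Where a symbol had several rows, the one with the highest mean was used. Genes named outside this rule were chosen after their values had been seen: in the report these are examples with overlapping intervals or under the filter (such as OAS1, MKI67, CDKN1A, CDKN2B, TRIB3, IL6, COL1A1, FN1, DNMT1, TET1, MUC1, KRT7, KRT8, KRT18, CD68 and PTPRC) and further interferon list members (ISG15, IFI6, DDX58, IFIH1 and IRF7). The values of some genes are not reported here.

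Total reads are unknown, since the table holds no counts. Among 2973 genes with 1 annotated start site and values between 0 and 1 FPKM in both columns, the most frequent induced to uninduced ratio was 0.86 (131 genes within 0.01, against 22 at 0.75 times that ratio). If this is the ratio of the value of 1 fragment, the induced column had 1.16 times the depth of the uninduced column. The FPKM sums were 553536 and 482743, and RNU6-1315P, at 2.47% of the uninduced sum and listed at 0 induced, is left out of the genes named by rule because of its prefix. The lower bound was 0 for 7275 kept genes uninduced and 7187 induced.

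The criterion was tested on simulated data: for 14178 genes, values were drawn around the mean of the columns, with the distance to the upper bound taken as 2 SD. It called 2 of 50 genes changed by 1 log2 unit, 16 of 50 changed by 2, 24 of 50 changed by 4, 26 of 50 changed by 6, and 34 of 13978 unchanged genes. Of 200 random lists 11 lay outside the central range, and all 50 lists shifted by 1 log2 unit were found. Transcript length and GC content came from a GRCh38 annotation by Ensembl identifier, for 97.1% of the kept symbols; no coordinate was taken from it.

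The alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter, a mean of at least 5 FPKM, scaling of the columns to the same sum, the same 75th percentile or the same distribution (quantile normalization), summing of rows with the same symbol, and a further requirement of a 2-fold difference. Added after the data had been seen were an interval of the difference that excludes 0 and values above 0 in both columns. The matching in 20 bins, which was run first, was kept as an alternative when the 100-gene window replaced it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.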

Results

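RNA was sequenced from BJ-5ta cells, a line of human foreskin fibroblasts immortalised with telomerase (hTERT), in a clonal derivative that carries a FOXA2 transgene under doxycycline control. FOXA2 is a forkhead transcription factor of the endoderm and liver that can bind its sites in closed chromatin. The labels give 2 samples grown without doxycycline and 2 samples given 0.5 µg/ml doxycycline. The table used here holds 1 FPKM value per gene for each group, with a deposited confidence interval, and no value per sample. The difference between the groups therefore has no replicate check, and no p-value, SD or n is given. The labels also describe an overnight mimosine treatment, which arrests cells in G1, without stating which cultures received it. At 1 FPKM or more, 13207 rows of the table were detected in the uninduced and 13915 in the induced column.

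The comparison of the induced with the uninduced column asked which genes differ in fibroblasts when FOXA2 is switched on. FOXA2 itself rose, from 4.82 FPKM (interval 0.526 to 9.12) to 104 FPKM (50.2 to 158), a ratio of 21.6, or 5.51 between the nearest interval bounds. Its row (ENSG00000125798) spans chromosome 20, 22561643 to 22566093, in hg19, and the value does not separate the transgene from the endogenous gene. Of its relatives, FOXA1 was at 1.04 FPKM uninduced and 1.63 FPKM induced with overlapping intervals, and FOXA3 was listed at 0 in both columns. Of 14319 genes kept, 104 rose and 65 fell, where a gene is said to rise or fall only if its 2 deposited intervals do not overlap. With a looser criterion added after the results had been seen, that the interval of the difference excludes 0, 180 rose and 159 fell. Interferon-stimulated genes led the genes that rose, and genes of mitosis were prominent among those that fell.

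The intervals were wide: in the uninduced column the upper bound lay a median of 101% above the FPKM. At least 2-fold differences on the log2(FPKM + 1) scale were seen for 1317 genes higher and 863 genes lower after induction, and 2011 of these had overlapping intervals. This balance depended on the settings: 1728 genes were higher and 613 lower with the columns scaled to the same sum, 959 higher and 1021 lower after quantile normalization, and 712 higher and 660 lower with a mean of at least 5 FPKM required. An overlap is no evidence that a gene stayed the same: in simulated columns with intervals of these widths, 2 of 50 genes changed by 1 log2 unit were called, 16 of 50 changed by 2 units, and 26 of 50 changed by 6 units. In the same simulation 34 of 13978 unchanged genes were called, beside the 104 and 65 called in the data, so some of these calls are expected to be wrong. The simulated noise came from the interval widths alone. Whether these widths include differences between cultures is not stated, so the share of wrong calls cannot be estimated from the simulation.

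**Figure D1:**
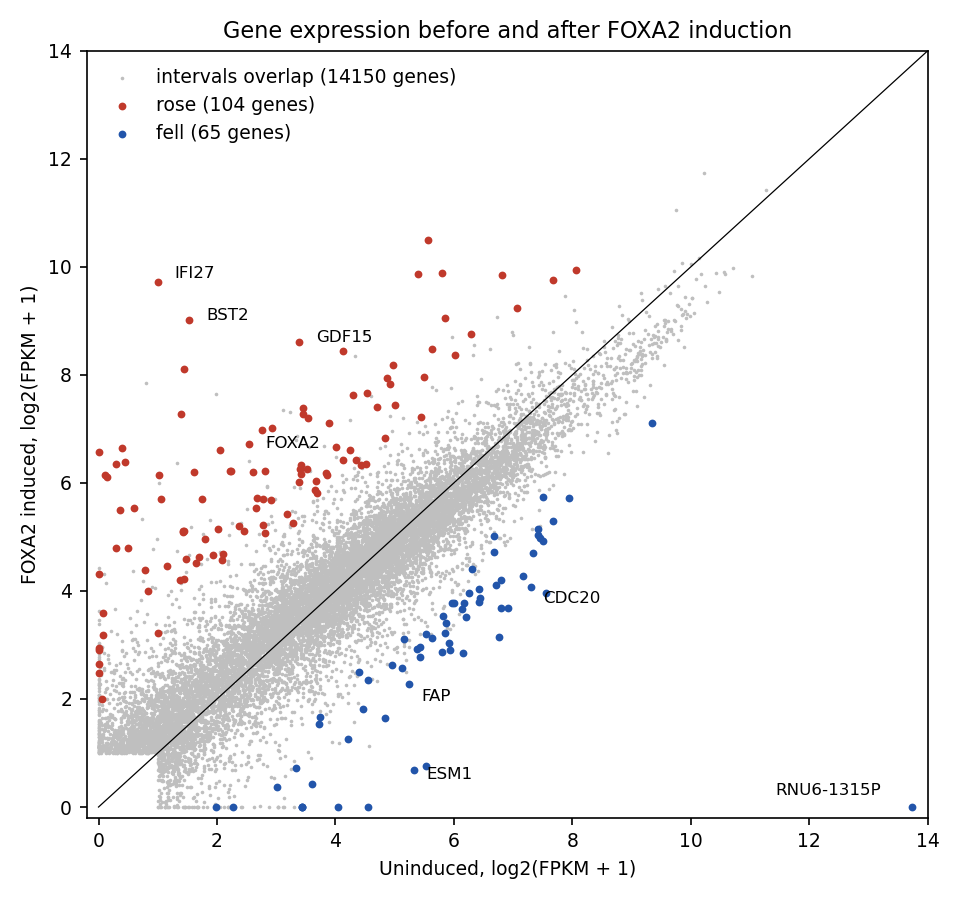
Gene expression before and after FOXA2 induction for the 14319 genes kept. Each point is a gene, with the uninduced value on the horizontal axis and the induced value on the vertical axis, both as log2(FPKM + 1); the 104 genes in red rose and the 65 in blue fell, by non-overlapping deposited intervals, and the line marks equal values.

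The 10 named genes with the largest increases included 6 interferon-stimulated genes. IFI27 (chromosome 14, 94571182 to 94583033) rose from 1.00 FPKM (interval 0 to 3.52) to 841 FPKM (343 to 1339), a log2 difference of 8.72. BST2, which tethers budding virus particles to the cell, rose from 1.90 FPKM (interval 0 to 4.55) to 514 FPKM (238 to 789). MX1 and MX2, antiviral dynamin-like GTPases, rose from 1.70 to 275 FPKM and from 0.363 to 82.8 FPKM. RSAD2, which encodes the antiviral enzyme viperin, rose from 0.107 to 67.8 FPKM, and IFI44L from 1.62 to 154 FPKM. The other 4 were CHRNA1, a muscle acetylcholine receptor subunit (0.0819 to 70.2 FPKM), MFI2, or melanotransferrin (0.225 to 80.4 FPKM), KHDC1L (0.320 to 99.0 FPKM) and a snoU13 copy, listed at 0 uninduced and 94.5 FPKM induced. The uninduced interval of snoU13 was 0 to 0, and its call was lost when values above 0 in both columns were required. The locus spans of MX1, RSAD2, CHRNA1, MFI2, KHDC1L and snoU13 in the table are shared with other kept genes, and 478 rows carry the snoU13 symbol, so reads may not be assigned to 1 gene with certainty.

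Among the 10 named genes with the largest decreases, 2 act in mitotic entry and exit. CDC20 (chromosome 1, 43824626 to 43828874), an activator of the anaphase-promoting complex, fell from 156 FPKM (interval 72.6 to 239) to 15.9 FPKM (3.09 to 28.7), and CDCA3 fell from 70.1 to 6.22 FPKM. ESM1, a secreted proteoglycan, fell from 39.1 to 0.602 FPKM. SERPINB7 fell from 186 to 14.6 FPKM, TMEM158 from 107 to 7.84 FPKM, and OXTR, the oxytocin receptor, from 119.7 to 11.8 FPKM. TNFSF18 fell from 27.6 to 2.13 FPKM and VGF, a neuropeptide precursor, from 11.2 to 0.346 FPKM. TRBC2, annotated as a T cell receptor constant segment, fell from 45.3 to 0.691 FPKM, and AC118278.1 was at 15.6 FPKM uninduced and listed at 0 induced. The induced interval of AC118278.1 was 0 to 0, and its call was likewise lost when values above 0 in both columns were required. CDCA3, OXTR and AC118278.1 share their locus spans with other kept genes.

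Interferon response genes were higher as a group. All 22 kept members of the list were at least 2-fold higher after induction, and 14 of them rose. The list median was 4.51 on the log2 scale, against a central 95% range of -0.35 to 0.21 for random lists matched on expression. After IFI27, BST2, MX1 and RSAD2, the members that rose included ISG15, a ubiquitin-like modifier (40.9 to 928 FPKM), IFI6 (46.1 to 1452 FPKM), the RNA sensors DDX58 (6.59 to 128 FPKM) and IFIH1 (3.13 to 96.4 FPKM), and the transcription factor IRF7 (6.02 to 74.0 FPKM). OAS1, an oligoadenylate synthetase, was at 0.748 FPKM uninduced and 228 FPKM induced, with overlapping intervals.

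Cell cycle genes were lower as a group. In the G2/M list all 22 kept members were at least 2-fold lower after induction, 10 of them fell (19 if the interval of the difference need only exclude 0, and 8 with the columns scaled to the same sum), and the median was -2.23 (random range -0.33 to 0.19). AURKA, a mitotic kinase, fell from 84.6 FPKM (interval 35.2 to 134) to 12.8 FPKM (1.17 to 24.4), CCNB1, or cyclin B1, from 181 to 29.3 FPKM, and PLK1, another mitotic kinase, from 103 to 16.3 FPKM. The proliferation marker MKI67 was at 34.6 and 6.19 FPKM, with overlapping intervals. In the G1/S list of DNA replication genes, all 22 kept members were below 0, 15 by at least 2-fold, and the median was -1.40 (-0.34 to 0.19). Of these, UHRF1 alone fell, from 55.4 FPKM (interval 26.0 to 84.8) to 10.5 FPKM (3.31 to 17.8). If the interval of the difference need only exclude 0, MCM2, RRM1, TYMS and TK1 fell as well. In the p53 and senescence list 9 of 18 kept members were at least 2-fold higher, 1 rose, and the median was 0.97 (-0.32 to 0.28). The member that rose was GDF15, a stress-responsive cytokine, from 9.48 FPKM (interval 0 to 19.1) to 389.9 FPKM (176 to 603). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 132 and 292 FPKM, and CDKN2B at 6.19 and 51.2 FPKM, both with overlapping intervals. Which cultures received mimosine, which arrests cells in G1, is not stated in the labels.

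**Figure D2:**
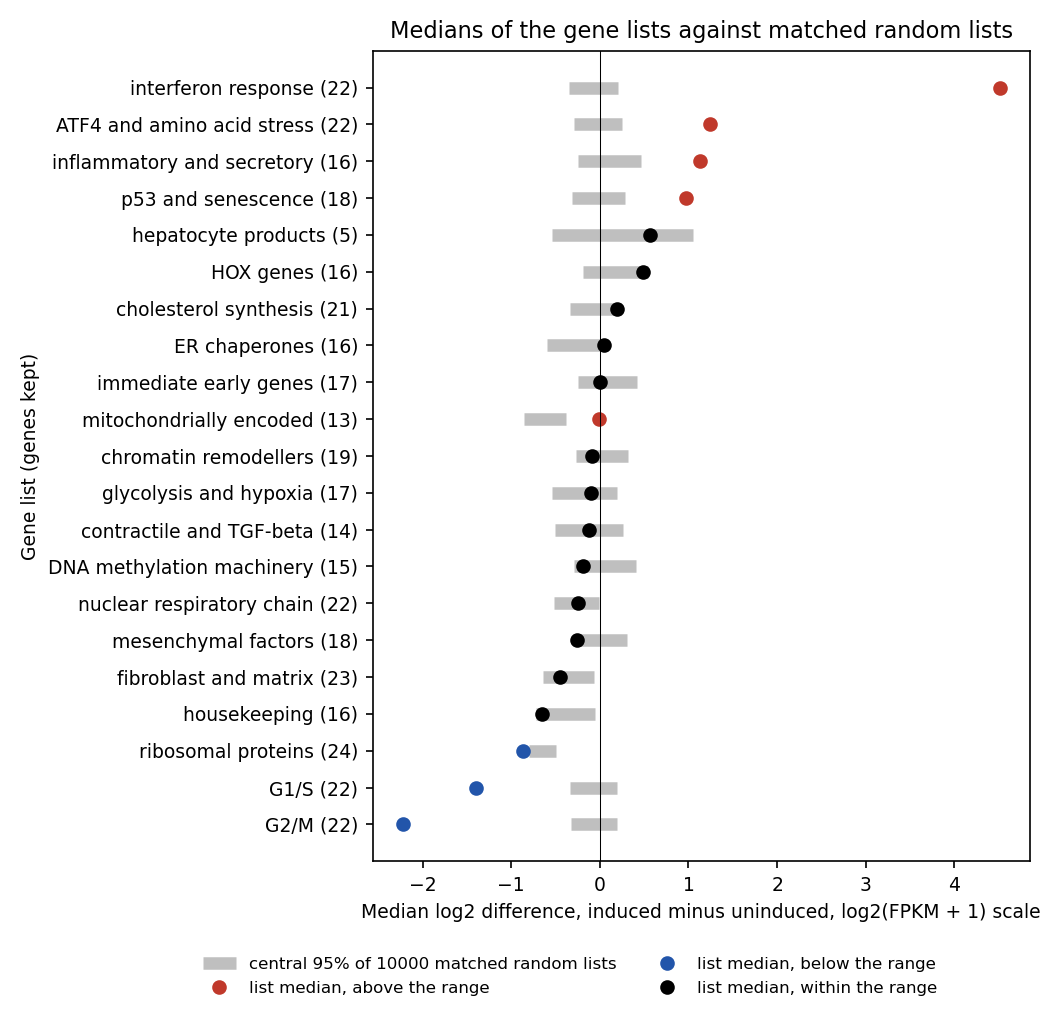
Median log2 difference, induced minus uninduced on the log2(FPKM + 1) scale, of the 21 gene lists with at least 5 kept genes (points), with the central 95% of 10000 random lists matched on expression (grey bars). The interferon list lies highest at 4.51 and the G2/M list lowest at -2.23; the median of the mitochondrially encoded genes lies near 0.

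Stress and secretory genes were higher as groups, with few members passing the criterion. In the list of ATF4 targets and amino acid stress genes 13 of 22 kept members were at least 2-fold higher, and 3 rose: GDF15, shared with the p53 list, ASNS, or asparagine synthetase (13.3 to 71.9 FPKM), and PSAT1, of serine synthesis (20.5 to 79.7 FPKM). The median was 1.24 (random range -0.29 to 0.25). TRIB3, a stress-induced pseudokinase, was at 11.9 and 46.8 FPKM with overlapping intervals. By the looser criterion, that the interval of the difference excludes 0, TRIB3, CHAC1, VLDLR and SESN2 rose as well, and SESN2 is also in the p53 list. In the inflammatory and secretory list 9 of 16 kept members were at least 2-fold higher, the median was 1.13 (-0.25 to 0.47), and the cytokine LIF alone rose, from 1.79 FPKM (interval 0 to 3.87) to 23.2 FPKM (4.01 to 42.4). After quantile normalization the intervals of LIF overlapped. IL6 was at 3.53 and 22.4 FPKM, with overlapping intervals. The endoplasmic reticulum chaperones, such as CALR (628 and 541 FPKM) and HSP90B1 (479.8 and 358 FPKM), had a median of 0.04 within the range of -0.59 to 0.07, and 0 of 16 rose or fell; after quantile normalization the median, 0.25, lay above its range.

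Genes of the tissues in which FOXA factors act were mostly near or below the detection filter in both columns. Of the hepatocyte products 5 of 24 were kept, with a median of 0.57 (-0.54 to 1.05). Of these, 4 were above 0 and 1 below, AFP, at 3.34 FPKM uninduced and 0.318 FPKM induced with overlapping intervals. FGB, the fibrinogen beta chain (chromosome 4, 155484108 to 155492238), rose from 0.289 FPKM (interval 0 to 1.54) to 44.2 FPKM (13.3 to 75.1). Its partner chains FGA and FGG were under the filter, at 0.00678 and 0.0173 FPKM induced. ALB, or albumin, was listed at 0 uninduced and 0.0434 FPKM induced, and TTR at 0 in both. The kept genes were too few for a median in the lists of endoderm factors (1 of 13), liver factors (4 of 18), pancreas, gut and lung genes (2 of 23) and epithelial genes (3 of 22), and 0 of these kept genes rose or fell. HNF4A, SOX17 and GATA4 were listed at 0 in both columns. MUC1, an epithelial mucin, was at 3.15 and 17.1 FPKM and KRT7, an epithelial keratin, at 2.58 and 23.0 FPKM, both with overlapping intervals. The other 2 genes of the epithelial list above the filter, the keratins KRT18 (149 and 67.7 FPKM) and KRT8 (90.6 and 65.8 FPKM), had lower values induced, also with overlapping intervals.

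Fibroblast genes were expressed in both columns. In the fibroblast and matrix list 23 of 24 members were kept, with a median of -0.45 inside the random range of -0.65 to -0.07 (-0.04 after quantile normalization), and FAP, a surface protease of activated fibroblasts, alone fell, from 36.8 FPKM (interval 14.3 to 59.4) to 3.84 FPKM (0 to 9.41). COL1A1 was at 754 and 498 FPKM and FN1, or fibronectin, at 863 and 2111 FPKM, with overlapping intervals. None of the 18 kept mesenchymal factors, 14 contractile and TGF-beta genes or 16 HOX genes rose or fell, and their medians were -0.25 (-0.30 to 0.31), -0.12 (-0.51 to 0.26) and 0.49 (-0.19 to 0.54). After quantile normalization they were -0.18, -0.06 and 0.22, each within its range. PRRX1, a mesenchymal homeobox factor, was at 106 and 166 FPKM, FOSL1 at 187 and 78.5, TAGLN at 478 and 179, TPM2 at 587 and 351, HOXA10 at 33.3 and 61.8, and HOXA9 at 35.1 and 28.8.

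In the DNA methylation list 1 of 15 kept members fell, UHRF1, which guides maintenance methylation and is also in the G1/S list. DNMT1, the maintenance methyltransferase, was at 58.4 and 28.7 FPKM, and TET1, a demethylating enzyme, at 0.486 and 1.86 FPKM, with overlapping intervals. The list median was -0.19 (-0.29 to 0.40). None of the 19 kept chromatin remodellers and modifiers rose or fell, with a median of -0.09 (-0.27 to 0.32); SMARCB1 was at 65.8 and 48.1 FPKM and HDAC2 at 106 and 85.2 FPKM.

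**Figure D3:**
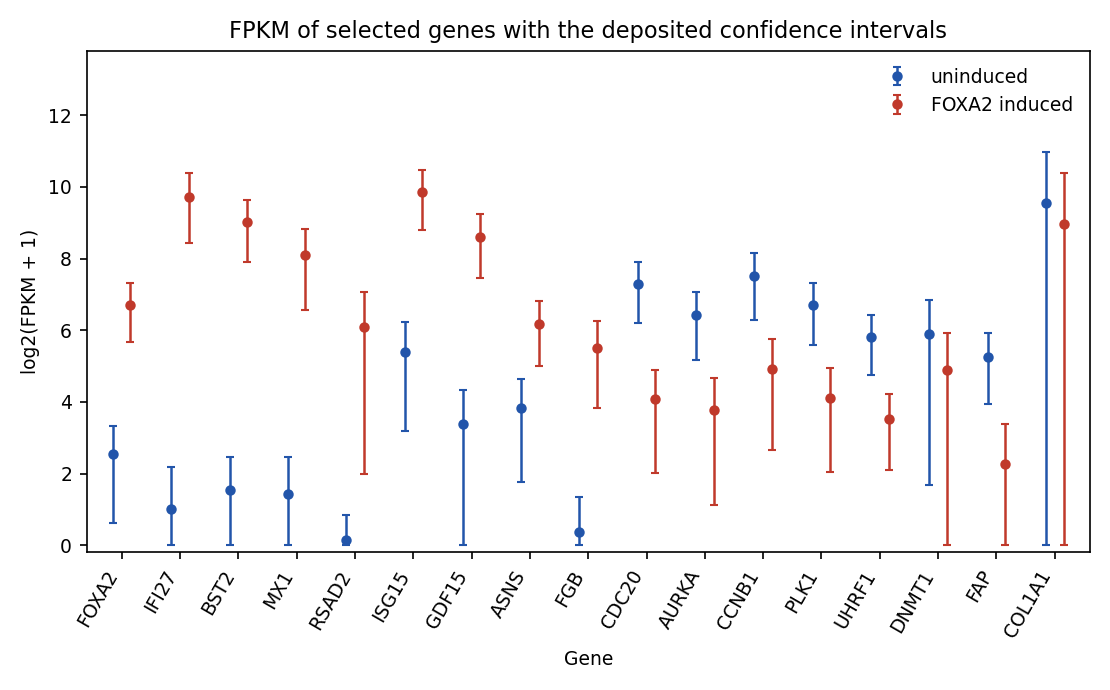
FPKM of 17 selected genes in the uninduced (blue) and FOXA2 induced (red) columns, on a log2(FPKM + 1) axis. Bars are the deposited confidence intervals, whose level the table does not state; those of FOXA2, IFI27 and CDC20 do not overlap between the columns, and those of DNMT1 and COL1A1 do.

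In the deposited values, highly expressed genes were lower as a class. The median log2 difference was 0.35 for genes with a mean under 3 FPKM, -0.13 between 30 and 100 FPKM and -0.68 at 300 FPKM or more. The ribosomal protein list had a median of -0.86, with all 24 members below 0 and 0 that fell, just outside the range of -0.81 to -0.50 for random lists of equally abundant genes. After quantile normalization its median was -0.39, against a range of -0.34 to 0.00. RPL4 was at 1064 and 563 FPKM and RPS18 at 956 and 578 FPKM. Housekeeping genes had a median of -0.66 (-0.72 to -0.06), and -0.31 after quantile normalization, with ACTB at 1534 and 932 FPKM; B2M, an antigen presentation gene in that list, was at 1199 and 3397 FPKM with overlapping intervals, which separated after quantile normalization. The 13 mitochondrially encoded genes had a median of -0.015, above the range of -0.86 to -0.38 for equally abundant genes; MT-CO1 was at 925 and 1069 FPKM and MT-CO2 at 1132 and 1150.3 FPKM. With random lists matched in 20 expression bins, the mitochondrially encoded list lay inside its range and the housekeeping list below its range.

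Metabolic and immediate early genes lay within their random ranges and had 0 members that rose or fell. The medians were -0.25 for nuclear respiratory chain genes (-0.52 to -0.01), -0.10 for glycolysis and hypoxia genes (-0.53 to 0.19), 0.19 for cholesterol synthesis (-0.34 to 0.24) and -0.0029 for immediate early genes (-0.25 to 0.42). LDHA, or lactate dehydrogenase A, was at 940.1 and 366 FPKM, ENO1 at 749 and 289, ATP5B at 344 and 262, ATP5A1 at 272 and 222, FDPS at 97.8 and 49.0, FDFT1 at 88.2 and 57.4, KLF6 at 47.2 and 45.4, and IER3 at 48.5 and 43.7. After quantile normalization the medians were -0.06 for the respiratory chain, -0.27 for glycolysis, 0.09 for cholesterol synthesis and -0.05 for immediate early genes, each within its range. Markers of other cell types were mostly under the filter: 3 of 10 keratinocyte, 3 of 10 immune, 3 of 10 melanocyte and neural, 0 of 10 endothelial and 0 of 10 fat and muscle genes were kept, and 0 of them rose or fell. Among the immune markers, PTPRC, the pan-leukocyte CD45, was at 0.547 and 1.30 FPKM, and CD68, a lysosomal glycoprotein of macrophages, at 94.0 and 178 FPKM.

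In all, 5 of the 21 lists with at least 5 kept genes lay above and 3 below their random ranges, where 1.05 outside would be expected by chance for lists of unrelated genes. With no filter on low values 8 more lists had enough genes, and 11 of 29 lay outside: the same 8, and above their ranges the pancreas, gut and lung list (0.18, range -0.03 to 0.11), the epithelial list (0.22, range -0.04 to 0.17) and the immune markers (0.29, range -0.12 to 0.27), most of whose members are under the filter. Scaling both columns to the same FPKM sum moved the median of all kept genes from 0.05 to 0.23. Relative to the median of all kept genes as deposited, the interferon list lay at 4.46, the G2/M list at -2.28 and the ribosomal protein list at -0.92. No sample with doxycycline and without the transgene was among those used here, so the differences belong to induction and drug exposure together.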

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

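The interval of the difference and values above 0 in both columns were chosen after the results had been seen, as was the 100-gene window of the reported ranges, in place of the 20 expression bins run first; the other alternatives were planned. No paired analysis was possible because the table holds 1 value per group and none per sample, and the planned limma and camera fits, their variants, fry, the replicate block and the fits leaving out a library were not run for that reason. FOXA2 rose, and the interferon, ATF4, p53 and inflammatory lists lay above and the G2/M, G1/S and ribosomal lists below their ranges, under every alternative run. When the interval of the difference had to exclude 0, a looser criterion by construction, 180 genes rose, 159 fell, and 19 of 22 G2/M genes fell. With a mean of at least 5 FPKM, which removes low genes, 712 genes were at least 2-fold higher and 660 lower. Scaling to the same sum gave 123 that rose and 56 that fell. After quantile normalization more genes were at least 2-fold lower (1021) than higher (959), and a pseudocount of 0.1 FPKM gave 1972 higher and 1091 lower. The mitochondrially encoded list, near 0 as deposited, was at 0.18 with the same sum and 0.021 with the same 75th percentile, signs that follow from the construction, since both move nearly all genes by a similar amount: relative to the median of all kept genes it went from -0.068 to -0.047 with the same sum. After quantile normalization it was at 0.42; the cause was not tested. It lay above its range each time. With no filter 11 lists lay outside, the further 3 being among 8 lists that only then had enough genes. In 20 expression bins that list was inside its range and the housekeeping list below it. Of 605 comparisons of named genes with an alternative, 3 lost the call (LIF, snoU13 and AC118278.1), 1 gained it (B2M) and 0 reversed. Many of these comparisons could not lose a call, so the count says little about how stable the calls are. The pseudocounts and the filters on low values do not enter a call, and the interval of the difference is a looser criterion. The 2-fold requirement left the 104 and 65 calls unchanged. Depth is unknown, and the wide intervals limit what could be called: 16 of 50 simulated genes changed by 2 log2 units were.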

Other observations

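The genes and groups in the next 2 paragraphs, and the tests of expression matching, of transcript length and GC content, of blood cell genes, of doxycycline samples, of IFNB1 and of TFRC, were chosen after the results had been seen, as was the 100-gene window of the random lists. The 3 scalings were planned, and the limits for their tests were set after the unscaled and before the scaled medians had been seen. Antigen presentation genes were among those that rose, such as HLA-B (111 to 916 FPKM), HLA-C (202 to 863 FPKM), HLA-F (9.90 to 166 FPKM) and the peptide transporter TAP1 (22.2 to 203 FPKM), while HLA-E, B2M, TAP2, TAPBP, PSMB8, PSMB9, PSMB10 and NLRC5 had overlapping intervals. STAT2, a transducer of interferon signals, rose from 31.1 to 172 FPKM. The chemokines CXCL10 and CXCL11, also inducible by interferon, were at 0.123 and 0.0658 FPKM in the induced column. The complement protease gene C1R (30.6 to 288 FPKM) rose, while C1S, CFB and SERPING1 had overlapping intervals, and of 7 lysosomal genes examined CTSK (77.6 to 429.8 FPKM), LGMN (168 FPKM induced) and GPNMB (16.6 to 84.4 FPKM) rose.

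Of 7 Notch pathway genes examined, the ligand JAG1 (2.25 to 23.8 FPKM) and the target HEY1 (2.13 to 21.8 FPKM) rose. The target HES1 (5.88 and 16.4 FPKM) and the receptors NOTCH1, NOTCH2 and NOTCH3 had overlapping intervals, and HEYL was under the filter. NUPR1, a stress-induced nuclear protein, rose from 3.68 to 73.9 FPKM, INHBA, the activin A subunit, from 1.22 to 21.1 FPKM, and SOX4 from 5.83 to 51.0 FPKM. Of 5 pregnancy-specific glycoprotein genes examined, PSG5 fell, from 171 to 34.4 FPKM. LMNB1, or lamin B1, was at 74.4 and 17.2 FPKM, and TERT, which the line carries as a transgene, at 331 and 108 FPKM, both with overlapping intervals.

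The interferon list was higher in the induced column by a median of 4.51. Scaling of the columns is argued against as the cause, since the list lay 4.46 above the median of all kept genes as deposited. The 3 scalings could decide little, because the FPKM sums (553536 and 482743) and the 75th percentiles (35.6 and 34.7) were close. The lowest median over them was 4.55. Other differences between libraries were not tested. Immune cells in the induced culture are argued against by 6 of the 10 immune markers, picked after the results as abundant in blood cells, none of which had an upper bound above 3.40 FPKM, although CD68, another of the 10, was at 94.0 FPKM uninduced and 178 FPKM induced with overlapping intervals, CD14 was at 0.823 and 2.15 FPKM, and the marker list lay above its range with no filter (median 0.29). Doxycycline and FOXA2 cannot be told apart as the source, because 0 samples used here had the drug without the transgene. Interferon beta made by the induced cells may contribute and stays open: IFNB1 was listed at 0 uninduced and at 1.17 FPKM induced, with an interval of 0 to 2.67.

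The G2/M list was lower by a median of -2.23. A trend with abundance is argued against as the whole cause, since lists matched on expression ranged from -0.33 to 0.19. Scaling is likewise argued against, since the list lay at -2.28 relative to the median of all kept genes as deposited. The 3 scalings, with a highest median of -2.04, could again decide little. Mimosine in the induced cultures alone could lower these genes and stays open. The mRNA of TFRC, which rises under iron chelation, differed by -1.40, opposite to that effect. Its intervals overlapped, although by the looser criterion, that the interval of the difference excludes 0, TFRC fell. A single gene does not decide the question. Slower division after FOXA2 induction may equally lower the G2/M genes, and was not tested.

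The ribosomal protein list was lower by a median of -0.86. Scaling to the same sum (median -0.66) or the same 75th percentile (-0.83) could again decide little, since the columns were close in both. Quantile normalization brought the median to -0.39, the highest over the 3 scalings. It removed part of the difference, and the rest argues against scaling as the whole cause. Other abundant genes were lower too: random lists matched on expression had a median of -0.49 and a range of -0.73 to -0.15 with 131 ribosomal genes never drawn, and of -0.68 and -0.81 to -0.50 with them. A trend with abundance could account for part of the list's difference. Whether it accounts for all of it stays open, since -0.86 lay outside either range, but by less than 0.5 times the width of that range, the limit set. Transcript length and GC content with abundance stay open on the same ground, with a median residual of -0.40 against a lower limit of -0.35, and no biological explanation was tested.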
